A study of Arabidopsis thaliana with 12 samples.

How the data were processed

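RNA bound by fluorescently tagged fibrillarin was profiled by crosslinking and immunoprecipitation followed by sequencing (CLIP-seq). Per the labels, seedlings of Arabidopsis thaliana Col-0 grown for 14 days on Murashige and Skoog plates were crosslinked with ultraviolet light, RNA was recovered after proteinase K digestion, and libraries were made with a NEBNext small RNA kit. There were 12 libraries in 3 groups of 4 numbered replicates: GFP alone, GFP-FIB1 and CFP-FIB2. The groups and the replicate numbers were taken from the sample titles and genotype labels.

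The authors deposited 1 peak list per library without a header. Each line gives a region, a strand, a p-value and a name, and the p-value column is the authors' own value for each peak, at most 0.0500. The name holds the gene locus or an intergenic number, the number of the peak and a whole number of at least 3, which the authors deposited without saying what it is. It was read as the reads in the peak: within each library its Spearman correlation with the p-value was between −0.973 and −0.995. Peaks were called per library and not on pooled samples, so replicates can be compared but a gene without a peak may still have reads. The submitters' processing notes name DESeq2, with no version. The aligner, peak caller, genome build, duplicate removal and filters are not given in the sources used here. No molecular identifiers are stated, so reads may include PCR copies. The total depth of the libraries is unknown, and depth below means reads in peaks.

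Gene names and coordinates were compared with RefSeq annotation of TAIR10.1. Of 633752 peaks named for a gene, 624188 had their locus in this annotation, 99.9% of these lay inside its bounds and 100% on its strand, so its coordinates were used. Mitochondrial peaks were used by gene name only, so mitochondrial protein-coding genes were not separated from other mitochondrial genes. The 61 mitochondrial genes tested had median log2 fold changes of 0.12 for GFP-FIB1 and 0.04 for CFP-FIB2 over GFP. Overlapping peaks of 1 library were reduced to the one with most reads, which removed 4107 peaks (0.396%). A peak was assigned to the first of 12 classes it overlapped by at least 1 nt on its strand. Annotated 25S genes were lacking around the nuclear 18S and 5.8S genes, so the 3600 nt downstream of each nuclear 5.8S gene was taken as the 25S region, a choice made after the files were seen. One 5.8S gene, AT2G01020, is named 5S in the annotation's product field.

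The annotation held 287 snoRNA genes. By name or by C, D, H and ACA box motifs, 163 were called box C/D, 50 H/ACA and 74 were left unclassified, and 70 lay inside protein-coding genes. For each snoRNA gene the share of 25-nt words found elsewhere in the genome was computed: 30 genes share over 50% of their words and 174 share none, and reads of the former may belong to copies.

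Per-library values (number and length of peaks, shares of peaks and reads, snoRNA genes with a peak, covered rRNA length) were compared with two-sided exact permutation tests over the 70 splits of 4 against 4 libraries, whose smallest p is 0.0286, and adjusted by the Benjamini-Hochberg method. Shares of peaks were planned, and shares of reads were added once the names were seen to hold reads. Stratified permutations within batches gave the within-batch p.

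Gene values were the reads in all peaks of a gene. The plan named a negative binomial count model for whole-number reads and a presence test otherwise. The number stands inside a name whose meaning the sources do not state, so no count model was run, and limma was fitted to log2(RPM + 1), a choice made after the data were seen. The presence test was also run: a gene counts as present with 1 peak or more, and presence in 4 of 4 against 0 of 4 libraries was tested with Fisher's exact test. RPM are reads in peaks relative to the reads in peaks of tested genes, scaled by a TMM factor computed with trims of 30% on log ratios and 5% on levels. The filter asked for 10 reads at median depth in at least 4 libraries and 15 in all, which left 19868 genes. Fold changes of low genes are lowered by the pseudocount of 1. A gene without a called peak counts as 0 even if it had reads, which can overstate a rise over GFP. In GFP replicate 1 only 64 of the 163 box C/D genes had a peak. All 12 libraries entered 1 fit with a mean-variance trend, and an adjusted p under 0.05 counted as a call. Gene lists were tested with camera at a preset correlation of 0.01 and again with the correlation estimated from the data. Genes of a list were also adjusted over the list alone.

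The groups, the comparisons, the gene lists and most of the other settings tried were set before the data were examined. The lists were all snoRNA, box C/D, H/ACA and U3 snoRNA, spliceosomal snRNA, the signal recognition particle RNA with RNase P and MRP RNA (1 member tested), nuclear and organellar tRNA and rRNA, mRNAs of C/D and H/ACA snoRNP proteins, nucleolin mRNAs, cytosolic ribosomal protein mRNAs (found by symbol or description, so a few organelle-type proteins such as RPL9 are included), light-harvesting and Rubisco mRNAs as leaf background, chloroplast protein-coding genes and the mRNAs that host snoRNA.

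Named genes followed a rule set beforehand: the FIB1 and FIB2 genes, up to 12 snoRNA genes with the largest log2 fold change among those past the threshold with all 4 tagged libraries above GFP, up to 8 of other classes by the same rule, up to 6 with the largest fall in all 4 libraries, and up to 4 members of each list with the smallest p. Since the planned fit called no gene, the rule was applied to the calls of the fit with a batch term. Genes outside the rule are said to be chosen after their values were seen.

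Batches were sought because libraries of different groups resembled each other. A first clustering, of log2 values into 3 clusters, split off GFP-FIB1 replicate 1 alone. In all 64 clusterings were run over 4 gene sets, and the one of deviations from group means over protein-coding genes was taken. Its 3 batches of 4, 3 and 5 libraries appeared in 31 of 32 clusterings of deviations and in 8 of 32 of log2 values, and batch A stood against the rest in 45 of 64. The batch term was chosen after seeing the data and after the planned fit had called no gene. It uses libraries of both tagged groups and GFP in every batch.

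Same-numbered libraries of the tagged groups deviated together (r of 0.50, 0.41, 0.31 and 0.41 for replicates 1 to 4). They also share a batch, so pairing by number cannot be told apart from batch. With GFP the same-numbered libraries were less evenly alike. The deviations of GFP replicates 1 to 4 correlated at 0.59, −0.03, 0.27 and 0.56 with GFP-FIB1 and at 0.52, −0.28, 0.18 and 0.46 with CFP-FIB2. Over all groups 10 of 12 same-numbered pairs exceeded 0.1. Only 6 of 12 libraries correlated best with the same number in another group. GFP replicates 2 and 3 lie in other batches than the tagged replicates of their number. A fit with the numbers as a block left 0 calls between the tagged groups and called 139 and 138 genes against GFP.

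Simulated data held known changes in 10 to 25 tested genes per size and direction (24 or 25 for rises). These genes were drawn at random and the noise was independent between genes, so the shares called may not hold for snoRNA. Among 17596 genes tested, the planned fit of GFP-FIB1 against GFP called 17 of 25 genes (68.0%) raised by a log2 of 4, 6 of 25 (24.0%) at 3 and 0% at 2 and 1. For CFP-FIB2 against GFP (16533 genes tested) the shares were 56.0%, 36.0%, 4.00% and 0%. With the batch term they were 88.0% and 60.0% (18388 genes tested) and 96.0% and 64.0% (17722 genes tested) at 4 and 3. Falls were called less often, at most in 16.7% without and 35.3% with the batch term. The exact tests matched an independent implementation in 50 simulated data sets.

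Alternatives covered scaling, pseudocount, filter, peak threshold, an equal number of 33773 peaks per library, overlap, strand, the replicate block, batches and leaving out each library. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 and R 4.3.3 with limma 3.58.1 were used.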

Results

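Fibrillarin is the methyltransferase of box C/D small nucleolar ribonucleoproteins, which place ribose methyl groups on ribosomal RNA at sites chosen by a guide snoRNA. FIB1 and FIB2 are fibrillarin genes of Arabidopsis, and the series asked which RNAs their products bind. RNA crosslinked by ultraviolet light and immunoprecipitated from 14-day-old Col-0 seedlings was sequenced from plants expressing GFP-FIB1, CFP-FIB2 or GFP alone as the negative control. The 3 groups held 4 replicates each, and the 12 deposited peak lists, called separately for each library, held 1037099 peaks.

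Depth differed widely within every group. The GFP libraries held 37832, 59551, 131708 and 81539 peaks in replicates 1 to 4, with 2811379, 4571150, 11568238 and 7378040 reads in peaks. For GFP-FIB1 the peaks numbered 33990, 135487, 91612 and 79833, with 4045675, 10095037, 6673203 and 5577714 reads. For CFP-FIB2 they numbered 66641, 116387, 127061 and 75458, with 7749681, 10805243, 8454161 and 12438185 reads. After overlapping peaks were reduced to 1, the mean was 84873 ± 41597 peaks (SD, n = 4) for GFP-FIB1, 95988 ± 29725 for CFP-FIB2 and 77387 ± 40125 for GFP, and the exact permutation p was 0.800 and 0.486 against GFP and 0.686 between the tagged groups. Covered length was 937644 ± 468225 nt, 1156003 ± 233085 nt and 869650.2 ± 419707 nt, with exact permutation p of 0.771, 0.314 and 0.486. All 18 pairs of libraries within a group differed by far more than sampling noise, with a chi-square per degree of freedom of 43.7 to 501, so no pair was taken for a repeat deposit of 1 library, which does not make them separate biological replicates. The labels do not say that replicates came from separate cultures, so every p-value measures only the spread between these libraries, which may be technical.

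The libraries fell into 3 batches found from the peak lists and not given by the labels. Batch A held GFP replicates 1 and 2 with replicate 1 of GFP-FIB1 and of CFP-FIB2. Batch B held GFP replicate 3 with replicate 2 of each tagged protein, and batch C held GFP replicate 4 with replicates 3 and 4 of each. Over 4455 protein-coding genes, libraries of 1 batch correlated at r of 0.42 to 0.82, batch A with the other libraries at 0.13 to 0.28, and batch B with batch C at 0.49 to 0.66. These correlations are across genes, which are not independent replicates.

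The first comparison asked which RNAs were recovered with GFP-FIB1 beyond the GFP background. Box C/D snoRNA, the guides of ribose methylation, rose from 0.315% ± 0.257 (SD, n = 4) of the reads in peaks with GFP to 9.33% ± 6.13 (SD, n = 4) with GFP-FIB1. All 4 GFP-FIB1 libraries lay above all 4 GFP libraries (exact permutation p = 0.0286, the smallest 4 against 4 can give, and 0.0429 adjusted over 3 box classes). Box H/ACA snoRNA, which guide pseudouridylation and carry dyskerin instead of fibrillarin, held 0.0891% ± 0.109 against 0.0265% ± 0.0156 (SD, n = 4 each, exact permutation p = 0.229). Replicate 2 alone held 0.252%, and without it the H/ACA difference of 0.0626 points was 0.00830. The snoRNA with no assigned box rose from 0.0411% ± 0.0234 to 0.804% ± 0.513 (exact permutation p = 0.0286, adjusted 0.0429), again in 4 of 4 libraries. For every H/ACA read there were 151 ± 118 C/D reads with GFP-FIB1 and 13.7 ± 14.1 with GFP (SD, n = 4 each, exact permutation p = 0.0286, adjusted 0.0429 over 3 comparisons, with 4 of 4 libraries higher). Among the GFP libraries replicate 4 had 34.7 and the others 5.96 to 7.85, and the difference of 137 fell to 90.1 without GFP-FIB1 replicate 4.

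All snoRNA together held 0.855%, 15.7%, 10% and 14.4% of the reads in peaks in GFP-FIB1 replicates 1 to 4, and 0.0721%, 0.297%, 0.412% and 0.751% in the GFP replicates. The exact permutation p was 0.0286, and 0.286 when adjusted over 12 RNA classes. Within batches the mean difference was 9.12 percentage points, with an exact stratified permutation p of 0.111, the smallest that its 18 orders allow. A sum of reads over called peaks moves with how much was called: snoRNA peaks covered 7000.5 ± 2954 nt with GFP-FIB1 and 5860.0 ± 1968 nt with GFP (exact permutation p = 0.571, adjusted 0.857). A snoRNA peak held 1018 ± 759 reads on average against 67.9 ± 52.6 (SD, n = 4 each, exact permutation p = 0.0571, adjusted 0.0857).

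**Figure D1:**
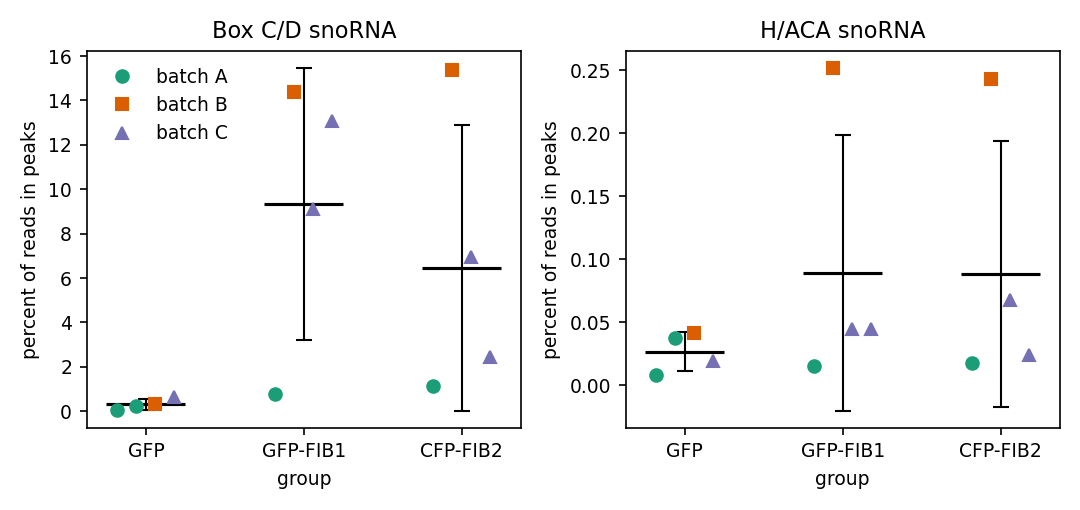
Percent of reads in peaks that lay in box C/D snoRNA (left) and box H/ACA snoRNA (right) in each library of the 3 groups, with the marker and colour giving the batch and the bar the mean ± SD of 4 libraries. The box C/D mean is 0.315% with GFP, 9.33% with GFP-FIB1 and 6.47% with CFP-FIB2, and the H/ACA means are 0.0265%, 0.0891% and 0.0879%.

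Among single snoRNA genes, AT5G02665 (box C/D, chromosome 5, 5674408 to 5674499, minus strand) held 13.8 ± 25.4 scaled reads in peaks (RPM) with GFP and 571 ± 400 with GFP-FIB1 (SD, n = 4 each), a log2 fold change of 6.60 ± 1.27 (SE). The box C/D gene AT1G06263 (chromosome 1, 10308751 to 10308840, plus strand, within the protein-coding gene AT1G29465) went from 2.05 ± 2.94 to 197 ± 170, and AT1G06233 (chromosome 1, 10300351 to 10300453, plus strand) from 11.8 ± 12.1 to 582 ± 278. These 3 genes share 52.9%, 56.1% and 46.8% of their 25-nt words with other places of the genome, so their reads are uncertain. The 92 tested box C/D genes with no shared word had a median log2 fold change of 4.21, and the 20 with over 50% of their words shared 4.09 (with the batch term 3.54 and 2.99). Of those without a shared word, AT1G20015 (chromosome 1, 6941285 to 6941373, plus strand) had a log2 fold change of 6.13 ± 1.36, and AT1G05993 (chromosome 1, 9076304 to 9076386, minus strand) of 5.87 ± 1.38. SNOR108 (AT5G41471, chromosome 5, 16598796 to 16598905, plus strand) rose from 1.48 ± 1.44 to 75.4 ± 43.9 RPM, a log2 fold change of 4.91 ± 0.87. In each of these 6 genes all 4 GFP-FIB1 libraries lay above all 4 GFP libraries, and the limma p adjusted over the 250 snoRNA genes alone was 0.00438 or less. For genes named by the largest rise this separation was a condition of the naming rule.

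Across the 153 box C/D genes tested the median log2 fold change was 4.20 (quartiles 3.38 to 4.99), and all 153 were positive. In GFP replicate 1 the median log2 level over these genes was 0, so genes without a called peak may raise fold changes over GFP in both comparisons. The 41 H/ACA genes had a median of 0.88 with 32 positive, and the 56 unclassified genes a median of 2.29. GFP has 2 libraries in batch A and GFP-FIB1 only 1, and with the batch term these medians were 3.34, 0.58 and 1.82. Adjusted over the list alone, limma called 135 of the 250 snoRNA genes higher and 0 lower, and 178 higher and 1 lower with the batch term. Adjusted over each class alone it called 125 of 153 box C/D genes, 0 of 41 H/ACA genes (2 at an unadjusted p under 0.05) and 10 of 56 unclassified ones, and with the batch term 142, 2 and 32. Complete separation of the groups was seen upward in 54 snoRNA genes (21.6%, against 1.43% by chance), of which 46 were box C/D. The 1 H/ACA gene that lay below GFP in all libraries, AT1G06467, held 53.0 ± 27.0 and 14.2 ± 4.47 RPM (log2 fold change −1.71 ± 0.86, limma p adjusted over the snoRNA alone 0.0944).

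Over all 19868 genes tested, limma without a batch term called 0 genes, with a smallest adjusted p of 0.202. At an unadjusted p under 0.05 it gave 349 higher and 236 lower genes, and the presence test on 34490 genes gave 23 with a peak in 4 GFP-FIB1 and 0 GFP libraries and 16 the other way, with 0 past adjustment. With the replicate numbers as a block it called 139 genes. Leaving out GFP replicate 4 gave 8 genes and leaving out GFP-FIB1 replicate 1 gave 6. The count over the list alone was 65 without GFP replicate 1, 83 without GFP-FIB1 replicate 2 and 85 without either GFP-FIB1 replicate 3 or 4. With the 3 batches as a term, added after the data were examined, 115 genes were higher and 14 lower, and 106 of the higher ones were snoRNA (92 box C/D, 1 H/ACA, 13 unclassified). That total of 129 became 68 without GFP replicate 3, 82 without GFP replicate 4, 66 without GFP-FIB1 replicate 2 and 82 without GFP-FIB1 replicate 4.

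**Figure D2:**
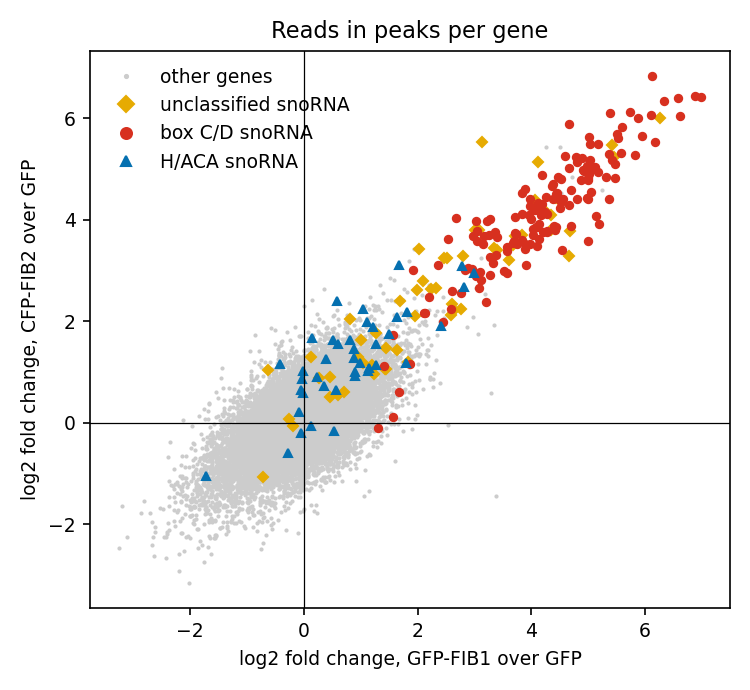
Log2 fold change of each tested gene for GFP-FIB1 over GFP (horizontal axis) and CFP-FIB2 over GFP (vertical axis), without a batch term, with box C/D snoRNA as red circles, H/ACA snoRNA as blue triangles, unclassified snoRNA as yellow diamonds and other genes in grey. The medians are 4.20 and 4.12 for box C/D, 0.88 and 1.17 for H/ACA, and 0.05 and 0.14 for all genes (the latter −0.10 with library totals), and because both axes share the GFP libraries some correlation arises with no effect at all.

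Outside snoRNA, 9 genes rose with the batch term. AT5G61310, a cytochrome c oxidase subunit Vc family gene of the mitochondrial respiratory chain (chromosome 5, 24653261 to 24654940, minus strand), held 5.90 ± 3.98 RPM with GFP and 143 ± 172 with GFP-FIB1 (batch-term log2 fold change 3.84 ± 0.60, limma adjusted p = 0.00133). The noncoding genes AT4G00975 (8.27 ± 4.40 to 142 ± 205) and AT1G09075 (1.61 ± 1.27 to 19.2 ± 7.61) had batch-term log2 fold changes of 3.46 and 2.74, and FYPP3, a protein phosphatase gene, had 2.71 with only 12.2 ± 13.9 RPM. The 4 genes were higher in 4 of 4 libraries, a condition of the naming rule. Without batch A the lower genes numbered 67 in place of 14. The 14 lower genes became 2 without GFP replicate 3 or GFP-FIB1 replicate 4, and 1 without GFP replicate 4, without GFP-FIB1 replicate 2 or with 2 batches. Of them, AT2G10280, an annotated pseudogene, went from 138 ± 93.6 to 18.7 ± 8.34, and UGT71C1, a UDP-glucosyltransferase gene, from 4.91 ± 1.19 to 0.370 ± 0.451 (batch-term log2 fold changes −2.82 and −2.24, limma adjusted p = 0.0256 and 0.0462). Another, AT2G29840, a RING/U-box gene, had −2.22, and these 3 were lower in 4 of 4 libraries, as the naming rule required.

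The fixed gene lists were compared with all other genes by camera with a preset correlation of 0.01. The 250 snoRNA genes together (median log2 fold change 3.57, 237 positive) and the box C/D genes were higher, with adjusted p of 9.73e-92 and 1.59e-121, and with an estimated correlation the adjusted p was 0.0491 for each. The H/ACA genes were higher with an adjusted p of 0.000327, and the adjusted p was 0.723 with an estimated correlation. U3 snoRNA, box C/D RNA needed for cleavage of the ribosomal precursor, had a median of 3.46 over U3D and U3B (adjusted p = 0.00607, and 0.248 with an estimated correlation), and adjusted over the list alone 1 of 2 was called. U3D (AT5G54075, chromosome 5, 21945349 to 21945709, minus strand) held 71.6 ± 64.2 and 1175 ± 773 RPM, and 62.9% of its words occur elsewhere. The 11 light-harvesting and Rubisco mRNAs, fixed as abundant leaf background, had a median of 0.94 with 11 of 11 positive (adjusted p = 0.0233, and 0.723 with an estimated correlation). Among them RCA, the Rubisco activase gene, held 20.5 ± 8.41 and 59.1 ± 34.5 RPM.

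Without a batch term no other list passed in this comparison. Adding the batch term brought chloroplast genes (9.49e-05), spliceosomal snRNA (0.00449) and ribosomal protein mRNAs (0.00588) past adjustment, all upward, and with an estimated correlation the adjusted p was 0.406 for each. The values that follow are without it. Spliceosomal snRNA (32 genes) had a median of 0.45 and cytosolic ribosomal protein mRNAs (73 genes) of 0.36, both with an adjusted p of 0.132, and nuclear rRNA (6 genes) had −0.45 at the same p. Nuclear tRNA (209 genes) had −0.19 (adjusted p = 0.169), organellar tRNA (27 genes) 0.05 (0.822) and organellar rRNA (4 genes) 0.10 (0.871). The mRNAs of C/D snoRNP proteins (6 genes, NOP56 among them) had −0.27 (0.361), those of H/ACA snoRNP proteins (4 genes, NAP57 among them) 0.38 (0.742) and the nucleolins NUC-L1 and NUC-L2 −0.28 (0.726). Chloroplast protein-coding genes (68) had 0.21 (0.399) and the mRNAs that host snoRNA in their introns (26 genes) 0.14 (0.995). The RNA of the signal recognition particle, AT7SL-1, went from 22 ± 30.9 to 1.35 ± 1.16 RPM (log2 fold change −2.01 ± 1.16, with overlapping groups). In each of these lists limma called 0 genes, over all genes and adjusted over the list alone, and the medians kept their sign under all 3 scalings.

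CFP-FIB2 was compared with GFP in the same way. The series has no group with CFP alone, so the fluorescent tag differs here as well. Box C/D snoRNA rose to 6.47% ± 6.44 (SD, n = 4) of the reads in peaks from 0.315% ± 0.257, and the unclassified snoRNA to 0.554% ± 0.469 from 0.0411% ± 0.0234, each in 4 of 4 libraries (exact permutation p = 0.0286, adjusted 0.0429). H/ACA snoRNA held 0.0879% ± 0.106 against 0.0265% ± 0.0156 (exact permutation p = 0.314). Much of the excess came from CFP-FIB2 replicate 2: without it the differences fell from 6.15 to 3.18 points for box C/D, from 0.512 to 0.330 for unclassified and from 0.0614 to 0.00978 for H/ACA snoRNA. All snoRNA held 1.22%, 16.7%, 7.77% and 2.72% in replicates 1 to 4. The exact permutation p against GFP was 0.0286, and 0.343 over 12 classes, and within batches the mean difference was 7.28 points (exact stratified permutation p = 0.111, the smallest possible). The ratio of C/D to H/ACA reads was 82.9 ± 22.6 (exact permutation p = 0.0286, adjusted 0.0429, with 4 of 4 libraries higher). Covered snoRNA length was 7331 ± 1630.1 nt (exact permutation p = 0.314, adjusted 0.857), and the mean reads per snoRNA peak were 952 ± 912 (exact permutation p = 0.0286, adjusted 0.0857).

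AT1G20015 was the snoRNA gene with the largest rise, from 16.9 ± 20.2 to 1599 ± 1916 RPM (SD, n = 4 each), a log2 fold change of 6.83 ± 1.36 (SE). AT1G06237 (box C/D, chromosome 1, 10300489 to 10300565, plus strand) went from 82.5 ± 139 to 2072 ± 1548, AT3G03175 (box C/D, chromosome 3, 5387184 to 5387268, plus strand) from 46.6 ± 64.1 to 1633 ± 1733, and AT1G75166 (box C/D, chromosome 1, 28212518 to 28212603, plus strand) from 13.2 ± 10.9 to 1211 ± 1611. SNOR108 rose to 73.0 ± 34.2, a log2 fold change of 4.98 ± 0.87. In these 5 genes all 4 CFP-FIB2 libraries lay above all 4 GFP libraries, the limma p adjusted over the snoRNA alone was 0.00974 or less, and 47.2% of the words of AT1G06237 occur elsewhere in the genome. Again the naming rule asked for this separation in the genes with the largest rise. Of the named H/ACA genes, AT3G02725 (chromosome 3, 4411290 to 4411443, plus strand) held 1.39 ± 2.77 with GFP and 14.2 ± 16.3 with CFP-FIB2 (log2 fold change 2.67 ± 0.87), and its groups overlapped. With the batch term it was the 1 H/ACA gene called in each comparison (limma adjusted p = 0.0105 here and 0.00645 with GFP-FIB1).

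Box C/D genes had a median log2 fold change of 4.12 (quartiles 3.53 to 4.90, 152 of 153 positive), H/ACA genes of 1.17 (36 of 41) and unclassified ones of 2.51. The batches are uneven here too, and with the batch term these medians were 3.38, 1.07 and 1.79, and that of all snoRNA 2.68. Adjusted over the list alone, limma called 143 of 250 snoRNA genes higher and 0 lower, and 183 higher and 0 lower with the batch term. Adjusted over each class alone it called 124 box C/D, 0 H/ACA (5 at an unadjusted p under 0.05) and 15 unclassified genes, and with the batch term 143, 6 and 31. Complete separation upward was seen in 80 snoRNA genes (32.0%, against 1.43% by chance), 67 of them box C/D and 0 of them H/ACA. The number of snoRNA genes with a peak was 240.5 ± 21.7 with CFP-FIB2, 228 ± 41.1 with GFP-FIB1 and 181 ± 52.1 with GFP (SD, n = 4 each). The exact permutation p was 0.0571 for CFP-FIB2 against GFP, 0.229 for GFP-FIB1 against GFP and 0.686 between the tagged groups (adjusted 0.171, 0.343 and 0.686). A peak was found in 92.5% ± 5.04, 90.0% ± 9.38 and 69.3% ± 20.7 of box C/D genes and in 74.0% ± 16.2, 66.5% ± 23.8 and 60% ± 23.8 of H/ACA genes. The difference between these shares did not separate the groups (exact permutation p = 0.400, 0.343 and 0.714, adjusted 0.600, 0.600 and 0.714).

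Over all 19868 genes limma without a batch term again called 0 genes, with a smallest adjusted p of 0.194 and 463 higher and 99 lower genes at an unadjusted p under 0.05, and 138 with the block. The presence test on 34693 genes gave 35 with a peak in 4 CFP-FIB2 and 0 GFP libraries, 6 of them snoRNA, and 9 the other way, with 0 past adjustment. The count over the list alone was 71 without GFP replicate 1, 93 without GFP replicate 2 and 95 without either CFP-FIB2 replicate 2 or 4. With the batch term 112 genes were higher, 105 of them snoRNA (89 box C/D, 1 H/ACA, 15 unclassified), and 2 lower (27 without batch A). The total of 114 became 55 without GFP replicate 3, 70 without GFP replicate 4, 73 without CFP-FIB2 replicate 1 and 59 without CFP-FIB2 replicate 2. Of the 7 other genes that rose, AT5G61310 (to 166 ± 208 RPM) and the noncoding AT3G07215 (35.8 ± 47.8 to 730 ± 467, chromosome 3, 2296036 to 2297789, minus strand) had batch-term log2 fold changes of 3.98 and 3.96 (limma adjusted p = 0.00120 and 0.00175). Each rose in 4 of 4 libraries, a condition of the naming rule.

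By camera the snoRNA together (median 3.59, 242 of 250 positive) and box C/D were higher than other genes, with adjusted p of 7.82e-93 and 3.17e-113, and the adjusted p was 0.0475 for each with an estimated correlation. H/ACA snoRNA were higher at 5.39e-08, U3 snoRNA (median 3.43, 1 of 2 called adjusted over the list alone) at 0.00914, spliceosomal snRNA (median 0.66, 25 of 32 positive) at 0.0146 and the leaf mRNAs (median 0.85, 11 of 11 positive) at 0.0489. These 4 calls ended with an estimated correlation, where the adjusted p was 0.496, 0.286, 0.422 and 0.513. The snRNA gene U1.4, of the particle that recognises 5′ splice sites, held 7.40 ± 2.60 RPM with GFP and 20.9 ± 8.02 with CFP-FIB2. U4.2 held 2.68 ± 0.986 and 9.99 ± 6.02. In both all 4 CFP-FIB2 libraries lay above GFP, and limma called neither over all genes. With library totals the medians fell to 0.19 for snRNA (18 of 32 positive) and 0.34 for the leaf mRNAs (8 of 11).

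The remaining lists did not pass without a batch term, and limma called 0 of their genes, over all genes and adjusted over the list alone. Adding the batch term brought chloroplast genes (0.00871, up), ribosomal protein mRNAs (0.0489, up) and organellar tRNA (0.0126, down) past adjustment, and with an estimated correlation the adjusted p was 0.645, 0.649 and 0.649. Over its list alone 1 organellar tRNA gene was then called, upward (log2 fold change 4.55, adjusted p = 0.0117). Cytosolic ribosomal protein mRNAs had a median of 0.24 (adjusted p = 0.441), organellar tRNA −0.04 (0.229), organellar rRNA −0.16 (0.298) and the nucleolins −0.54 (0.298). AT7SL-1 had a log2 fold change of −0.86 ± 1.16. The median of all genes moved by 0.24 when library totals replaced the TMM scaling, from 0.14 to −0.10, and the medians of 5 lists turned negative with it. These were nuclear rRNA (0.20, adjusted p = 0.945), nuclear tRNA (0.03, 0.145), chloroplast genes (0.12, 0.838), H/ACA snoRNP mRNAs (0.11, 0.838) and host mRNAs (0.09, 0.838). For nuclear rRNA, nuclear tRNA and chloroplast genes the camera direction was down although the median was positive. The C/D snoRNP mRNAs had a median of −0.28, a mean of 0.07 and a camera direction of down (adjusted p = 0.374).

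Over the 12 RNA classes no share of reads passed adjustment in either comparison with GFP, with adjusted p of at least 0.286 and 0.343. Ribosomal RNA held 39.9% ± 8.79 of the reads in peaks with GFP-FIB1, 43.8% ± 11.2 with CFP-FIB2 and 51.2% ± 7.63 with GFP (SD, n = 4 each, exact permutation p = 0.0857 and 0.429, adjusted 0.286 and 0.468). Transfer RNA held 6.22% ± 2.73, 15.8% ± 19.9 and 5.09% ± 2.96 (exact permutation p = 0.543 and 0.400), and snRNA 0.139% ± 0.0231, 0.123% ± 0.0434 and 0.0902% ± 0.0330 (0.0857 and 0.2). By number of peaks, snoRNA took 0.828% ± 0.179 and 0.767% ± 0.155 against 0.478% ± 0.146, with an exact permutation p of 0.0571 and an adjusted p of 0.686 in each comparison. Protein-coding exons took 43.3% ± 1.06, 43.2% ± 7.06 and 44.5% ± 3.83 of peaks.

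Since the series concerns rRNA methylation, the length of each nuclear rRNA under a peak was compared. Of the 18S gene AT2G01010 (chromosome 2, 3706 to 5513, plus strand) 29.6% ± 4.30 was covered with GFP-FIB1, 26.3% ± 5.33 with CFP-FIB2 and 27.0% ± 2.25 with GFP. The 18S gene AT3G41768 (chromosome 3, 14197677 to 14199484, plus strand) was covered over 32.1% ± 5.36, 28.7% ± 8.94 and 29.9% ± 6.15, and the 5.8S gene AT3G41979 (chromosome 3, 14199753 to 14199916, plus strand) over 77.9% ± 24.3, 79.4% ± 12.2 and 78% ± 19.5. The 25S region of chromosome 2 was covered over 33.7% ± 2.18, 30.3% ± 2.86 and 34.2% ± 3.72, and that of chromosome 3 over 33.7% ± 0.778, 33.4% ± 7.39 and 33.1% ± 6.93 (SD, n = 4 throughout). Over the 6 rRNAs and 3 comparisons every adjusted exact permutation p was 0.514 or more. AT2G01010 held 30476 ± 9930 RPM with GFP and 13712 ± 4066 with GFP-FIB1, and all 4 GFP-FIB1 libraries lay below GFP (log2 fold change −1.15 ± 0.75, limma adjusted p = 1.00). It was the 1 of 6 nuclear rRNAs with this separation. How reads were placed between the 2 18S genes is not known, so the values of a single one are uncertain.

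The third comparison set the paralogs against each other. FIB1 carried GFP and FIB2 carried CFP, so paralog and tag cannot be told apart. Box C/D snoRNA held 9.33% ± 6.13 of the reads in peaks with GFP-FIB1 and 6.47% ± 6.44 with CFP-FIB2 (SD, n = 4 each, exact permutation p = 0.600, adjusted 0.900), and the C/D to H/ACA ratio of 151 ± 118 and 82.9 ± 22.6 had an exact permutation p of 0.429. The log2 fold change of GFP-FIB1 over CFP-FIB2 had a median of 0.08 over box C/D genes and −0.37 over H/ACA genes, neither past camera (adjusted p = 0.222 for each). The H/ACA gene AT5G01785 stood first in its class by p, with 6.73 ± 7.87 RPM with GFP-FIB1 and 16.6 ± 7.06 with CFP-FIB2 (log2 fold change −1.82 ± 0.90, limma p adjusted over the snoRNA alone 0.997). AT1G67430, a ribosomal protein L22p/L17e gene that hosts a snoRNA, held 8.11 ± 6.79 and 0.661 ± 1.32 (log2 fold change 2.35 ± 0.69, limma adjusted p = 1.00), with overlapping groups. Adjusted over its list alone it was the 1 host mRNA of 26 that limma called with the batch term (adjusted p = 0.0230, and 0.0800 without the term).

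Between the paralogs limma called 0 of 19868 genes when adjusted over all of them, without and with the batch term, and 0 of 250 snoRNA genes adjusted over the list alone. At an unadjusted p under 0.05, 81 genes were higher with GFP-FIB1 and 182 with CFP-FIB2, and the presence test on 34759 genes gave 7 and 30 with 0 past adjustment. Within batches the snoRNA read share differed by 1.84 points (exact stratified permutation p = 0.417, smallest possible 0.0833). No list passed without a batch term, with adjusted camera p of 0.222 to 0.873, and with it only organellar tRNA did (0.0227, and 0.952 with an estimated correlation). The median of all genes was −0.10, and 0.18 with library totals. The medians were 0.35 for organellar tRNA, 0.24 for organellar rRNA, −0.53 for nuclear rRNA, 0.26 for the nucleolins, 0.21 for H/ACA snoRNP mRNAs, −0.35 for C/D snoRNP mRNAs, −0.29 for host mRNAs, 0.02 for U3 snoRNA and 0.08 for chloroplast genes. Those of nuclear rRNA and of snRNA (−0.36) turned positive with library totals. The medians of all snoRNA (−0.02) and nuclear tRNA (−0.16) were negative while camera read up and also turned positive with library totals, that of all snoRNA with the median of ratios too, and for ribosomal protein mRNAs (median 0.05, mean −0.01) and leaf mRNAs (0.08, mean −0.00) the signs also differed. In this comparison the self-test called 60% of 25 genes set to a log2 rise of 4 and 20% of 25 set to 3 (0% at 1 and 2, among 17996 genes tested). The fit with a batch term called 100%, 72%, 8% and 0% at 4, 3, 2 and 1 (24 or 25 genes each, among 17980 tested). A log2 rise of 2 or less would thus mostly be missed. Larger rises may be missed too. The planned fit called 0 of 153 box C/D genes against GFP, at median log2 fold changes of 4.20 (GFP-FIB1) and 4.12 (CFP-FIB2).

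In the fit with a batch term 101 genes were higher in both comparisons with GFP, 94 of them snoRNA, and 1 was lower in both. Independent lists of these lengths would share 0.648 and 0.00141 genes. Simulated unchanged groups set against the same GFP libraries had 0 higher genes in either list on average over 20 simulations. Their overlap of 0 was therefore fixed and says nothing about the 101 shared genes. With the GFP libraries split so that each tagged group had its own pair, 11 to 35 genes were higher in both over the 6 splits. Without the batch term 0 genes were shared, since limma called none in either comparison. The fold changes correlated across genes at r = 0.67 against 0.53 in the simulations, with a covariance of 0.331 against 0.184. Over the GFP splits r fell to between −0.00 and 0.28 and the covariance to between −0.00391 and 0.179. For snoRNA genes alone the covariance was 2.05 against 0.456, and 1.40 to 1.77 over the GFP splits.

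FIB1 (AT5G52470, chromosome 5, 21294147 to 21296819, plus strand) and FIB2 (AT4G25630, chromosome 4, 13074090 to 13076432, plus strand) each carry a box C/D snoRNA in an intron. Their own transcripts gave few reads: FIB1 had 22 in GFP replicate 2 and 30 in GFP replicate 3, and FIB2 had 82 and 9 in GFP replicates 3 and 4 and 5 and 24 in CFP-FIB2 replicates 1 and 3, with no peak in the other libraries, so neither was tested. U60.1F (AT5G52471, chromosome 5, 21295736 to 21295809, plus strand), in the intron of FIB1, had 85, 178, 29 and 140 reads in the GFP replicates. It had 269, 2572, 2044 and 3246 with GFP-FIB1, and 525, 2862, 1940 and 1097 with CFP-FIB2. Its log2 fold changes were 3.74 ± 1.11 and 3.53 ± 1.11, all tagged libraries lay above all GFP libraries, and with the batch term the limma adjusted p was 0.0242 and 0.0441. U60.2F (AT4G25631, chromosome 4, 13075563 to 13075635, plus strand), in the intron of FIB2, had 5, 48, 0 and 25 reads with GFP, 0, 191, 282 and 359 with GFP-FIB1, and 16, 194, 307 and 177 with CFP-FIB2. Its log2 fold changes were 2.21 ± 1.21 and 2.48 ± 1.21 with overlapping groups, and with the batch term the limma adjusted p was 0.75 and 0.828. These snoRNA genes were named because of their hosts, after their values were seen.

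**Figure D3:**
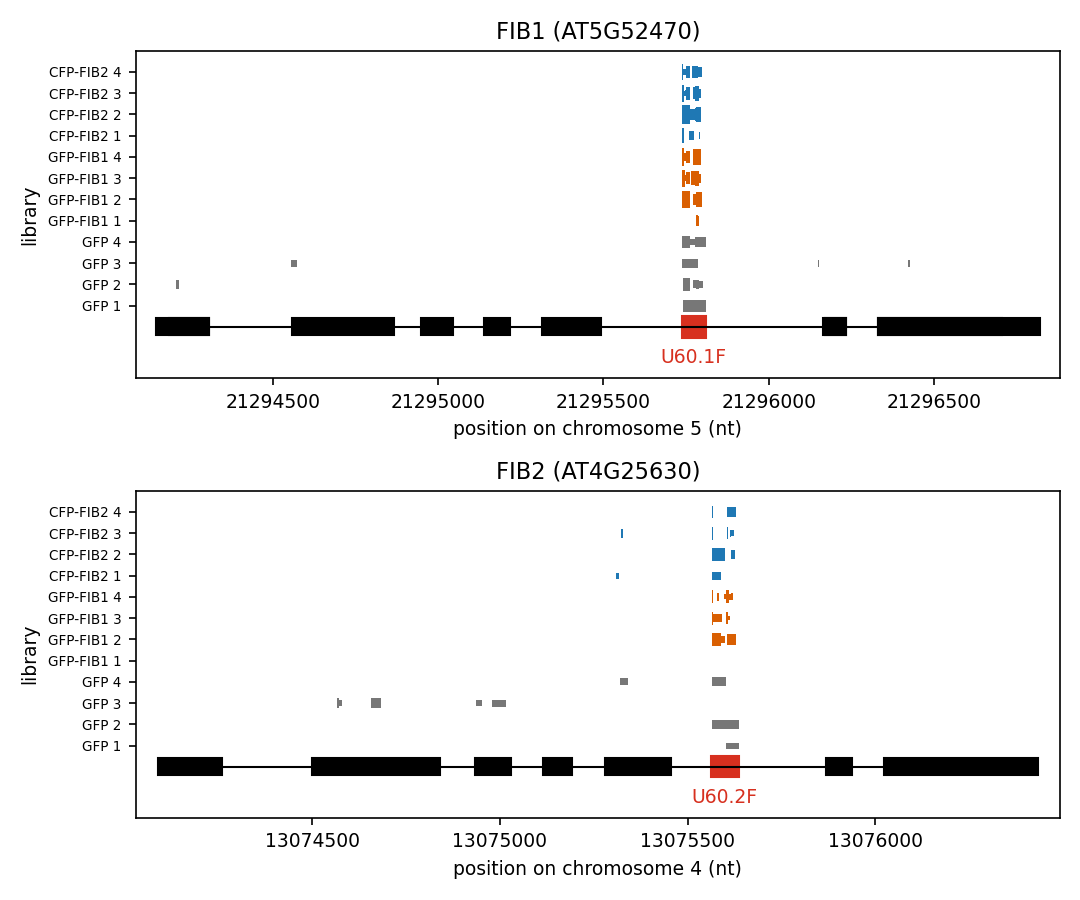
Maps of the FIB1 gene on chromosome 5 and the FIB2 gene on chromosome 4 (position in nt along the horizontal axis) with exons in black, the hosted snoRNA U60.1F and U60.2F in red and the peaks of each of the 12 libraries as bars whose height rises with log10 of the reads. Peaks lie mostly on the snoRNA: U60.1F has a peak in 12 libraries and U60.2F in 10, while the FIB1 transcript has one in 2 libraries and FIB2 in 4.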

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

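The tests of library depth, of batch, of GFP replicates 3 and 4 taken singly and of other splits of the libraries were chosen only after the result was seen.

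The strongest pattern was the excess of snoRNA reads in the tagged libraries, which is what box C/D ribonucleoproteins built around fibrillarin would give. Of the 7 tagged libraries with fewer reads in peaks than GFP replicate 3 (11568238 reads, 0.412% in snoRNA), 0% held as small a snoRNA share as that library, and the lowest held 0.855%, which argues against depth as the whole cause. The lowest tagged share was at least 2.88 times the highest GFP share in each of the 3 batches, which argues against batch, and the C/D to H/ACA read ratio rose in both comparisons (higher exact permutation p = 0.0286), which argues against a general background of small nuclear RNA. A binding of box C/D RNA by both paralogs is therefore a hypothesis consistent with these tests. What stays open is the size of the excess: tagged libraries held 0.855% and 1.22% against 0.0721% and 0.297% with GFP in batch A, 15.7% and 16.7% against 0.412% in batch B, and 2.72% to 14.4% against 0.751% in batch C. The 2.72% is of CFP-FIB2 replicate 4, where tRNA held 44.3% of the reads in peaks, which lowers the shares of other RNAs. After scaling, its median log2 level over box C/D genes was 8.27, against 7.71 to 8.90 in the other tagged batch C libraries.

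Counts of genes were compared with other splits of the 8 libraries into 4 and 4. With the batch term only splits that keep the numbers of each group in every batch can stand for chance. These are 18 for each comparison with GFP and 12 between the paralogs, too few for a share under 0.05. The real split gave 129 genes for GFP-FIB1 (highest other 17), 114 for CFP-FIB2 (highest other 1), each as many as in 1 split, and 0 between the paralogs (highest other 0, 12 of 12 as many). The batches were found from deviations from the means of the real groups, which may favour the real split. For the 250 snoRNA genes adjusted over the list alone, 3 of 35 splits gave as many as the real 135 for GFP-FIB1 (highest other 176, GFP replicates 1 to 3 with GFP-FIB1 replicate 1) and 2 of 35 as many as the real 143 for CFP-FIB2 (highest other 156, GFP replicates 1 to 3 with CFP-FIB2 replicate 1), so chance was not excluded there. Those splits put all of batch A on 1 side, and the batch-term counts are the within-batch values. Over all genes without a batch term the real counts were 0, so 35 of 35 splits gave as many in each comparison. The highest others were 832 for GFP-FIB1, with GFP and GFP-FIB1 replicates 1 and 2 on 1 side, 0 for CFP-FIB2 and 277 between the paralogs, with replicates 1 and 2 of both on 1 side. The split with 832 genes holds all of batch A on 1 side. Splits of the CFP-FIB2 and GFP libraries that do the same gave 0 genes. Those are partly other libraries, and the fit without a batch term misses many changes. Whether batch A accounts for the 832 thus cannot be decided from them, and the cause was not tested. Between the paralogs, 35 of 35 splits also gave as many as the real 0 when adjusted over the snoRNA list alone (highest other 45).

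The GFP libraries of batches B and C held more snoRNA reads than those of batch A, 0.412% and 0.751% against 0.0721% and 0.297%. If tagged libraries of the batch had spilled into GFP, box C/D genes would keep the tagged proportions. In GFP replicate 3, 36.2% of the box C/D genes expected to hold at least 20 reads held less than 0.5 of the expectation, which argues against such carry-over as the whole cause there. In GFP replicate 4 the lowest such share was 5.34% over its possible source libraries (up to 8.15%), with a Spearman correlation of 0.951 to 0.968 across genes, so carry-over and a real box C/D background cannot be told apart, because the share lies between the bounds set for them. Taken over both batches the lowest share was also 5.34%.

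In CFP-FIB2 replicate 4 the glutamate tRNA gene AT1G09110 (chromosome 1, 2939417 to 2939488) held 32.8% of the reads in peaks, against 1.52% to 9.71% in the other libraries of batches B and C and 0.0204% to 0.0738% in batch A. The TMM factor of that library was 0.283, and its cause was not tested. The gene was singled out after its values were seen. The 196 tested tRNA genes other than glutamate ones had a median log2 excess over the other 4 batch C libraries of 0.39 (95% bootstrap interval 0.13 to 0.70) while the 13 glutamate genes had 3.92, which argues against a general rise of tRNA. The other identical copies of this tRNA held 3.63% of its reads in that library and 0.821% to 5.02% in the other 11. Since all libraries share that placement, which of the copies the reads came from cannot be told apart. Those copies also held 1.23% of the reads in peaks there against 0.190% to 0.413% in the other batch C libraries, a log2 excess of 2.23, which argues against reads moved from the copies to this gene as the whole cause. No biological explanation was tested, as the labels name none for this library.

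Among 95 measures (42 per library and 53 genes) in 285 groups of 4 libraries, 46 single values lay far outside the other 3 of their group by Dixon's test, where chance at 1 in 20 gives 14.2. They fell on CFP-FIB2 replicate 2 (13), GFP replicate 4 (9), GFP-FIB1 replicates 1 (8) and 2 (6), CFP-FIB2 replicate 1 (4) and GFP replicates 2, 3 and 1 (3, 2 and 1), and many measures depend on each other. Replicates 3 and 4 of each tagged group, which share batch C, had 0. Apart from GFP replicates 1 and 2, which share batch A, each flagged library is the only one of its group in its batch. The chance rate ignores the batches, so batch and odd single libraries cannot be told apart here. By library, GFP-FIB1 replicate 1 stood out in its share of peaks in snRNA (0.195%), rRNA (1.87%), tRNA (1.17%), chloroplast (2.11%) and mitochondrion (1.54%) and of reads in protein-coding introns (1.23%). CFP-FIB2 replicate 1 did so in peaks in snRNA (0.175%) and rRNA (1.11%), GFP-FIB1 replicate 2 in H/ACA reads (0.252%) and GFP replicate 4 in reads in rRNA (39.7%) and other noncoding RNA (0.876%) and in the C/D to H/ACA ratio (34.7).

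Single genes are given in RPM. CFP-FIB2 replicate 2 was high in the snoRNA genes AT1G05993 (1451), AT1G06263 (549.6), AT1G06667 (707), AT1G20015 (4462), AT1G75166 (3601), AT2G08370 (1313), AT2G08390 (4918), AT2G43137 (1556), AT5G02575 (358) and U3B (5540.2), and in FYPP3 (35.3), AT4G00975 (730.1) and AT5G61310 (477). GFP-FIB1 replicate 2 was high in AT1G04527 (4598), AT2G08370 (1254), AT2G43137 (1307), AT4G00975 (448) and AT5G61310 (400.2). GFP replicate 4 was high in AT1G06237 (291), AT1G08643 (42.5), AT1G09915 (301), NOP56 (265), AT2G20722 (3.54) and AT5G02665 (51.9). Single high values were also seen in GFP-FIB1 replicate 1 for RPS15 (13.8) and NUC-L2 (19.0), in GFP replicate 1 for NUC-L2 (35.9), in GFP replicate 2 for AT1G04527 (90.5) and NAP57 (8.39), in GFP replicate 3 for the tyrosine tRNA gene AT2G07765 (0.821) and AT3G02725 (5.54), and in CFP-FIB2 replicate 1 for AT1G67430 (2.64) and AT7SL-1 (53.3). The 1 single low value was AT1G67430 at 0 in GFP replicate 2.

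A signal outside the annotation was seen on chromosome 1 from 27984836 to 27984877, minus strand, with a batch-term log2 fold change of 5.43 ± 0.65 for GFP-FIB1 over GFP (limma adjusted p = 0.0172) and 5.04 for CFP-FIB2 (0.0368). It was the 1 locus called in each of these comparisons among 5992 unannotated loci. Without the batch term limma called 0 of them in all 3 comparisons, with 63, 44 and 10 at an unadjusted p under 0.05.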

How the results depend on the processing

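The batch terms, the pseudocounts, leaving out batch A, the shares by snoRNA box, their ratio and the counts with a batch term or over the snoRNA list alone are tests chosen only after the result was seen. Of 5645 alternative values of 325 results, 5409 kept their side of the threshold or, for counts, stayed within 1.5 times. Another 121 passed the threshold, 67 no longer did, 47 counts moved beyond 1.5 times and 1 reversed. A change of sign was counted as a reversal only where a value passed the threshold. Peak shares, covered rRNA length, peak number, snoRNA genes with a peak and read shares of all snoRNA and of H/ACA kept their side. None of them was past adjustment in the first place. The H/ACA difference between the paralogs ran from −0.0531 to 0.0528 points. The box C/D and unclassified shares and the C/D to H/ACA ratio, added later, passed in all 5 settings that keep 12 libraries unpaired and in none of the 10 others, where no p under 0.05 can arise. Their differences from GFP (GFP-FIB1, CFP-FIB2) were 9.02 and 6.15 points, 0.763 and 0.512 points and 137 and 69.2 with the block (exact permutation p 0.125), 11.7 and 7.76, 0.988 and 0.652 and 164 and 68.1 without batch A (0.2), and, leaving out each library, 7.34 to 11.9 and 3.18 to 7.94, 0.612 to 1.00 and 0.330 to 0.668 and 90.1 to 171 and 62.6 to 76.3 (0.0571). The snoRNA read-share difference ran from 8.03 to 13.0 points for GFP-FIB1 and 3.52 to 8.69 for CFP-FIB2 over 16 settings (exact permutation p 0.0286 to 0.2, where 4 against 3 libraries can give 0.0571 at least). For all changes below the cause was not tested, and settings with fewer libraries have less power. With camera's estimated correlation the adjusted p was 0.723 and 0.496 for H/ACA, 0.723 and 0.513 for leaf mRNAs and 0.248 and 0.286 for U3 snoRNA (GFP-FIB1, CFP-FIB2), and 0.422 for snRNA in CFP-FIB2. With the batch term, camera with the preset correlation gave chloroplast genes 9.49e-05 for GFP-FIB1 and 0.00871 for CFP-FIB2, where its direction reversed from down to up, ribosomal protein mRNAs 0.00588 and 0.0489, snRNA 0.00449 for GFP-FIB1, and organellar tRNA 0.0126 for CFP-FIB2 (down) and 0.0227 between the paralogs. With the estimated one all ended (0.406 and 0.645, 0.406 and 0.649, 0.406, 0.649 and 0.952). Genes differing from GFP were 0 in both comparisons as planned, by limma, with 585 and 562 at an unadjusted p under 0.05. They became 139 and 138 with a replicate block, which joins GFP replicates 2 and 3 with tagged libraries of another batch. The batch term gave 129 and 114, and 2 batches 58 and 55. In the planned fit, leaving out batch A gave 4 and 1. Leaving out each library gave 0 to 8 for GFP-FIB1 (8 without GFP replicate 4, 6 without GFP-FIB1 replicate 1). The genes higher or lower in both became 102 with the batch term. Over the snoRNA list alone a pseudocount of 5 gave 86 in CFP-FIB2, and leaving out each library 65 to 186 in GFP-FIB1 (65 without GFP replicate 1) and 71 to 184 in CFP-FIB2 (71 without GFP replicate 1). With the batch term, a pseudocount of 5 gave 54 and 56 genes (51 and 54 higher snoRNA), leaving out batch A 265 and 219 (169 and 170), 2 batches 58 and 55 (55 and 54), and leaving out each library 66 to 166 and 55 to 145 (62 to 136 and 52 to 131 snoRNA), lowest without GFP-FIB1 replicate 2 for GFP-FIB1 and without GFP replicate 3 for CFP-FIB2. Library totals gave 1 gene between the paralogs with the batch term. Single named genes passed the threshold in 44 cases with the batch term, 37 with the block, 27 with 2 batches, 5 without GFP replicate 4 and 2 without GFP-FIB1 replicate 1. They make up 115 of the 121 values that passed. Genes named by the size of their change came from the batch-term calls, so their passing with that term was fixed by the choice. Total sequencing depth is unknown, and a gene under the peak caller's limit reads 0, so small differences and low genes stay out of reach. The alternative with a count model and its size factors was not run: the number in the peak names is used as reads, but the sources do not say that it is a count.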

Other observations

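The test of box C/D motifs in loci outside annotated snoRNA and the test of rRNA matches were set before the result was seen, while the tests of which loci passed used the batch term, which, like counting overlapping loci once, was chosen only after the result was seen.

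AT5G08155, an uncharacterised RNA gene of 186 nt (chromosome 5, 21990623 to 21990808, plus strand), held 42.1 to 1570.2 RPM in the GFP libraries, 368 to 45820 with GFP-FIB1 and 132 to 67732 with CFP-FIB2. Its batch-term log2 fold change was 3.93 ± 0.84 for GFP-FIB1 (limma adjusted p = 0.0256) and 3.27 for CFP-FIB2 (0.118), and its groups overlap. PRIN2, a gene needed for plastid transcription, had 3.30 ± 0.76 (0.0462) and 3.31 (0.05), with 6.55 to 184 RPM in GFP and 32.3 to 8391 in tagged libraries. MIR4228 (chromosome 1, 28889375 to 28889532, plus strand) had 2.83 ± 0.59 and lies inside the noncoding gene AT1G09915, which had 3.44 ± 0.75. Peaks were given to MIR4228 first, so the values of the pair rest on different reads, with top peaks at 28889520 and 28889563. Below, the pair is counted once because it overlaps, and whether it is 1 signal was not tested.

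Loci outside annotated snoRNA that rose with the batch term may be box C/D RNA that the annotation does not name. With overlapping loci counted once, 4 of 9 such loci (44.4%) had their top peak between a C box and a D box, against 1823 of 25170 other tested loci (7.24%, one-sided Fisher exact p = 0.00259). The motif search first asked for a terminal stem as well and missed most annotated box C/D genes, so the stem was dropped on annotated snoRNA alone, before the called loci were looked at. The final search finds 87.6% of 153 box C/D genes, 9.76% of 41 H/ACA genes and 21.4% of 56 unclassified ones. Those classes were themselves set mostly by the same C and D box motifs, so these shares are no independent measure of the search. The 4 are AT1G09075, AT1G09915, AT3G07215 and the unannotated locus on chromosome 1, which lies 45 nt from the snoRNA gene AT1G74456. The element of AT1G09915 (108 nt) has 1 mismatch in the C box. That of AT1G09075 (111 nt) begins at a C box with 1 mismatch, and a C box without a mismatch overlaps it. Both elements are near the longest spacing allowed, 110 nt from the start of the C box to the D box. AT1G09075 held only 7.43 to 33.6 RPM in the tagged libraries, so these 2 are weaker candidates. The element of AT3G07215 is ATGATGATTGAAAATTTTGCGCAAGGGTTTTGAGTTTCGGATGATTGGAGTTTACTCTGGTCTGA (65 nt) and that of the unannotated locus is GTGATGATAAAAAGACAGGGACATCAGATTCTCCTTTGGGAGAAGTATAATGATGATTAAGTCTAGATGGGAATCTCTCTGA (82 nt). The latter holds a 10 nt match to the 25S region, at position 2515 from its start, and 1 of the 4 had an rRNA match against 42 of the 1823 other motif loci (2.30%).

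Guides with an rRNA target might be bound more than orphan ones. Of 163 box C/D genes 90 have at least 10 nt complementary to nuclear rRNA next to a D box (30 to 18S, 4 to 5.8S and 56 to the 25S region), against a mean of 4.2 in 20 shuffles of the rRNA. The 89 tested genes with a match had a mean log2 fold change of 4.14 for GFP-FIB1 and the 64 without one 4.23 (difference −0.09, 95% interval −0.44 to 0.27). For CFP-FIB2 the means were 4.05 and 4.20 (difference −0.15, −0.52 to 0.22). The higher permutation p of the comparisons was 0.640, so no difference between genes with and without a match was found. A gene without an exact match of 10 nt may still guide rRNA methylation, so guides and orphans cannot be told apart here. The p and the intervals take genes as independent units, although the estimated correlation between box C/D genes was 0.584. They hold no spread between libraries, so they set no bound on the recovery of guides.

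Reads within box C/D genes lay at different places by batch. In the tagged libraries 19.2% and 17.2% of them fell in the last part of the gene, of 3 equal parts, in batch A, 59.4% and 57.4% in batch B and 35.1% to 38.4% in batch C. GFP libraries had 34.6% to 44.5%.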
